A study of Rattus norvegicus with 6 samples.

How the data were processed

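Liver RNA from 6 male Sprague-Dawley rats was measured on 1-colour arrays, 3 rats killed after isoflurane anaesthesia and 3 after CO2/O2 anaesthesia, with 1 rat per array. Per the labels' protocols, RNA was checked on a Bioanalyzer and 0.2 ug was amplified and labelled with the dye Cy3. Per the submitters' processing notes, images were read with Agilent Feature Extraction 10.7. The spot values deposited for each array are intensity values on a linear scale that Feature Extraction had corrected for background, per the file headers, with no scaling between arrays. The deposited value table holds, for each array, a ratio on a linear scale. Set against the scanner output, each of its columns was the processed intensity divided by 1 number close to the 75th percentile of that array, with no centring of probes; how the authors chose that divisor is not given in the sources used here. The medians of its columns were 0.0864, 0.0881 and 0.0868 for CO2/O2 replicates 1 to 3 and 0.0917, 0.0900 and 0.0905 for isoflurane replicates 1 to 3. The labels conflict on the corn oil vehicle, 5 mL/kg/day: the design text gives 3 days and the treatment protocol gives 9 weeks.

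For the main analysis, log2 of the processed intensity was reduced by each array's 75th percentile over the 61657 non-control probes, so that a value of 0 is that percentile. Each non-control probe had 1 spot. The 177 spots marked as outliers by the scanner software were left out, and saturated spots, of which there were none, would have been kept. A probe was tested where it was well above background on all 3 arrays of at least 1 group. Means, differences and standard errors came from limma 3.58.1 in R 4.3.3 (lmFit and eBayes). Benjamini-Hochberg adjustment of probes was over all those tested, with a threshold of adjusted p 0.05. Differences are isoflurane minus CO2/O2 on the log2 scale. File reading and plots used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.

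Probes were named by matching the accession on the array, without its version, to RefSeq genes of the assembly GRCr8, used for names only. Of 61657 probes, 27460 matched 1 gene, 0 matched several and 34197 were unmatched, giving 15284 genes. Unmatched probes were tested but are unnamed here, and genome positions are not given because the arrays' headers name another build. A gene was represented by its tested probe with the highest mean over all 6 arrays, and took the adjusted p of that probe. A gene that was not well above background on any array of a group is given as "at least N-fold": the brighter group's mean was set against the mean, over the arrays of the dimmer group, of the higher of the dim probe's own signal and the lowest signal among probes well above background.

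Before the data were examined, 34 gene lists, the tests, the alternatives and the rule for named genes were fixed. Lists with at least 5 tested members were tested with limma's camera at its preset correlation between genes of 0.01, and with smaller lists values only are given. Genes were named by this rule. Past the threshold, up to 12 genes with the largest rise and 12 with the largest fall would be named; as none passed, 6 genes per direction with the smallest unadjusted p were taken. Of each list, members past the threshold over all probes or adjusted over the list alone were taken, at most 6 by size, with those of largest moderated t added up to 2. Members of the clock, immediate early, carbonic anhydrase and other lists named beyond this rule were chosen after their values were seen, as were the 3 unnamed probes and the genes that varied between rats. Some genes that the rule takes, or that an alternative called, are not reported here.

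The alternatives were normexp background correction with an offset of 50, quantile normalization, median centring, the authors' value table, no filter on dim probes, a filter asking for signal above background on all 6 arrays, outlier-marked spots kept, eBayes with trend and robust, the replicate number as a block, the slide row as a block, the mean of a gene's probes, other thresholds, an estimated correlation in camera, limma's fry, and leaving out each array in turn. The spot columns held no mean signal, so normexp used the median signal. All 6 arrays lay on 1 slide with 1 scan time, so blocks for slide and scan date were not run. The test was checked on 20 simulated datasets of 34570 probes for isoflurane against CO2/O2. It recovered 62.8% of changes of 2-fold and 91.7% of changes of 4-fold, with 7.1% false among calls. Each dataset held 100 changes of each size, none among the dimmest probes. These rates need not hold where fewer probes change or for dim probes. An 11-gene list shifted by -0.35 was called in 20 of 20 datasets with the preset correlation and in 0 with an estimated one. The simulated probes varied independently of each other, whereas the same list had an estimated correlation of 0.667 in the data. These runs therefore do not show whether the preset correlation holds for that list. The number of arrays, 3 per group, limits the precision.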

Results

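Liver gene expression was measured in 9-week-old male Sprague-Dawley rats, an outbred stock, given corn oil at 5 mL/kg/day. The rats were killed after isoflurane anaesthesia (n = 3) or CO2/O2 anaesthesia (n = 3). Isoflurane is an inhaled anaesthetic, and CO2/O2 is a gas mixture used to render rodents unconscious. The comparison asks how the choice of anaesthesia before killing relates to the hepatic transcriptome. No group without anaesthesia was measured, so a difference cannot be assigned to either kind. Between 53.4% and 62.3% of probes were well above background per array, at 56.9%, 60.2% and 62.3% in CO2/O2 rats and 60.6%, 53.4% and 55.7% in isoflurane rats. The 75th percentile of signal lay between 912.5 and 998.3, and no spot was saturated. The spike-in series had slopes of 0.945 to 0.99 per array.

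Hepatic expression was much alike after both kinds of anaesthesia, and no named gene passed the test. Of 10609 genes tested, 0 reached an adjusted p of 0.05 in limma, the smallest adjusted p being 0.153. The adjustment was over all 34637 tested probes and not over genes. At an unadjusted p under 0.05 there were 799 genes, 302 higher and 497 lower after isoflurane, where 530 would be given by chance. The 95% confidence interval of the difference had a median half-width of 0.29 log2 units, and for 90.5% of genes it lay within 2-fold in either direction. A difference of at least 2-fold, whatever its p, was measured for 121 genes, or 1.14%. The values of both groups did not overlap for 14.2% of genes, against 10% expected by chance for 3 against 3. That expected value likewise takes no account of genes that vary together across arrays.

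Among 34637 probes, 3 passed the threshold, and none of them could be named. Probe A_44_P802347 was at least 12.1-fold higher after isoflurane (n = 3 per group; limma adjusted p = 0.00128), a bound because it was not well above background on any CO2/O2 array. Probe A_44_P492674 was lower after isoflurane by 1.34 log2 units (SE 0.083, limma adjusted p = 0.0325). Probe A_42_P540609 was lower by 1.37 log2 units (SE 0.087, limma adjusted p = 0.0325). These 3 probes lie outside the rule for named genes and were singled out after their values were seen.

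The 12 named genes with the smallest p, 6 in each direction, did not pass the threshold. Ces2e, a carboxylesterase of a family of close paralogs, had a log2 difference of -4.87 ± 0.46 (SE), or 29.3-fold lower after isoflurane, with 2 of the 3 isoflurane arrays above background (limma adjusted p = 0.153). Insig1, a sterol-responsive regulator of cholesterol synthesis, had a difference of -1.08 ± 0.13. Slc27a5, the bile acyl-CoA synthetase of bile acid conjugation, had -0.87 ± 0.11, and its other probe gave -0.90. Abcd2, a peroxisomal fatty acid transporter, and Trem1, a receptor on myeloid cells, were not above background on any isoflurane array, with differences of at least 1.1-fold and 1.31-fold. Ccdc112 had a difference of -0.60 ± 0.097. Zbtb16, a transcription factor induced by glucocorticoids, had 2.60 ± 0.43, with 0.56 at its other probe. Adat2, a tRNA deaminase subunit, and Heph, a ferroxidase, had differences of 1.02 ± 0.12 and 1.22 ± 0.16. Ten1, of the telomeric CST complex, had 1.29 ± 0.21 and Myo1e, an unconventional myosin, 0.64 ± 0.099. The homeobox gene Nkx6-3 had 0.51 ± 0.080, and its other probe gave -0.05. In all these genes the 3 values of each group did not overlap.

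**Figure D1:**
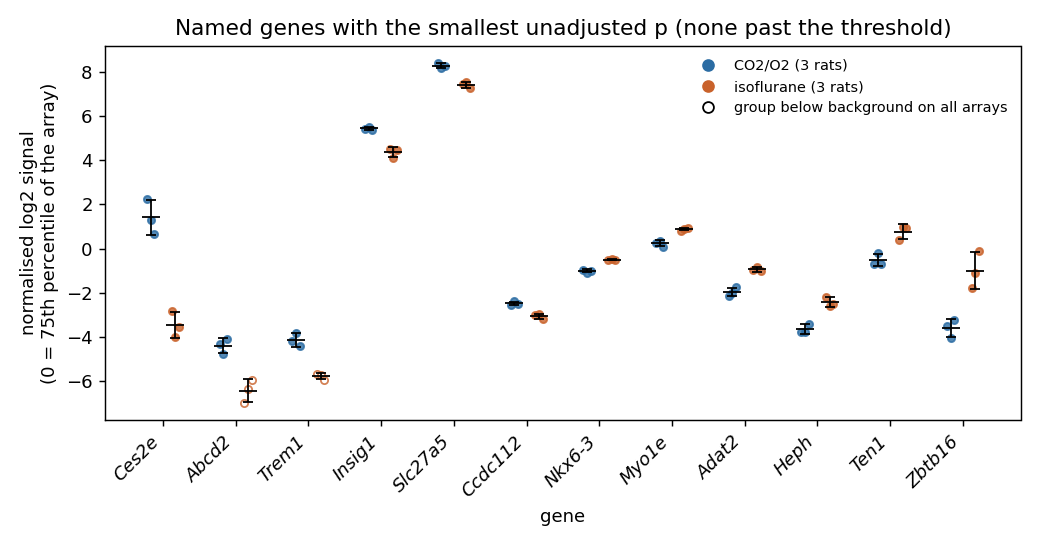
Normalised log2 signal per array, with 0 at the array's 75th percentile, of the 12 named genes with the smallest unadjusted p, 6 lower and 6 higher after isoflurane. Points are rats (3 per group), bars are the mean and SD, and open points mark a group not above background on any array; the values of each group do not overlap in these genes, and 0 of them passed the adjusted threshold.

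Markers of Kupffer cells, the resident macrophages of the liver, were lower after isoflurane. All 11 of 11 markers had negative differences, with a median of -0.32 log2 units (camera with the preset correlation, adjusted p = 1.52e-06). With an estimated correlation, camera gave an unadjusted p = 0.107 and adjusted p = 0.921, an adjusted value shared by all tested lists. That form of the test called a simulated shift of -0.35 in 0 of 20 datasets. Its lack of a call therefore does not decide against a shift. Adjusted over the list alone, 6 members passed, against 0 over all probes. These were Vsig4, a complement receptor (-0.62 ± 0.13), Clec4f, a Kupffer cell lectin (-0.50 ± 0.14), Csf1r (-0.45 ± 0.13, with 0.03 at its other probe), Cd5l (-0.40 ± 0.10), the complement gene C1qb (-0.32 ± 0.11) and Adgre1 (-0.30 ± 0.10). The mean over the 11 markers was 0.35, 0.21 and -0.04 on the CO2/O2 arrays and -0.09, -0.21 and -0.23 on the isoflurane arrays, relative to the mean of all arrays. With the slide row as a block the median was -0.32, which sets isoflurane replicate 1 alone against the CO2/O2 rats and rests on 1 rat for that arm. Array places were counted along slide row 1 and then on along row 2, which is also the order of the replicate numbers within each group. After a slope over these places shared by both groups, the difference in the mean of the 11 markers was 0.046 (SE 0.141), against -0.35 before.

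**Figure D2:**
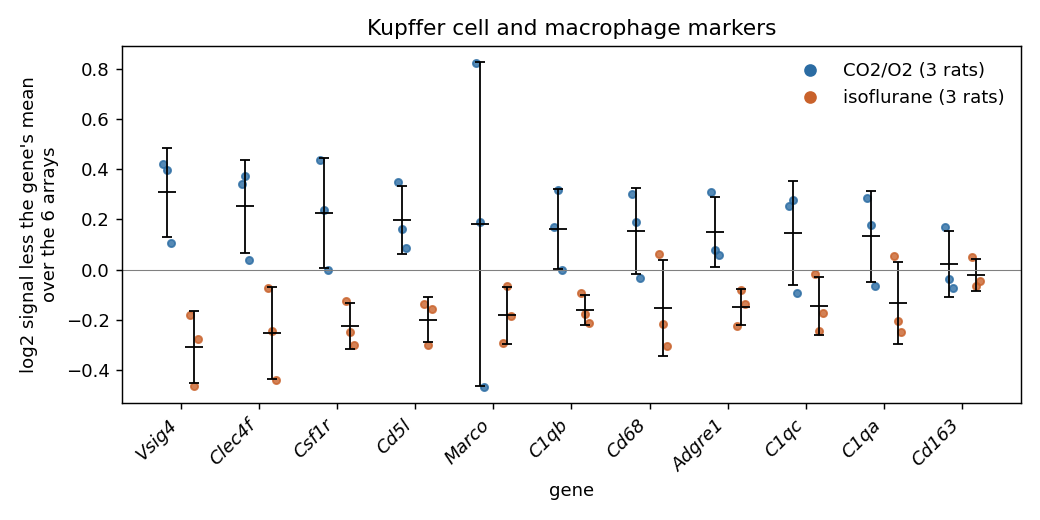
Log2 signal of each of the 11 Kupffer cell and macrophage markers less the gene's mean over the 6 arrays. Points are rats (3 per group) and bars are the group mean and SD; all 11 group means are lower after isoflurane, by 0.04 to 0.62 log2 units.

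Lymphocyte markers were lower in 10 of 10 members, with a median of -0.34 (camera with the preset correlation, adjusted p = 0.00269; adjusted p = 0.921 with an estimated correlation). Gzmb, a cytotoxic protease, had -0.76 ± 0.26 and Cd8a -0.54 ± 0.18; 0 members passed over the list alone. The list mean was 0.28, 0.26 and 0.00 on the CO2/O2 arrays and 0.01, -0.08 and -0.47 on the isoflurane arrays, in order of place on the slide. The call ended without isoflurane replicate 3 (median -0.22, adjusted p = 0.0818) and with the slide row as a block (median -0.17, adjusted p = 0.143). Erythroid markers had a median of -0.36 (6 of 7 lower, adjusted p = 0.0721). That list passed in 8 of 17 other settings, with adjusted p from 0.000559 without isoflurane replicate 2 to 0.64 without isoflurane replicate 3, and medians from -0.55 to -0.20 with an array left out. It had adjusted p = 0.921 with an estimated correlation and 0.859 with fry. Its members included values of -0.45 ± 0.16 for the globin Hbb, whose probes can share signal with Hbb-b1, and -0.73 ± 0.21 for the anion exchanger Slc4a1. Neutrophil markers had a median of -0.29 (S100a9 -0.55, S100a8 -0.43; adjusted p = 0.734). Sinusoidal endothelial markers had a median of -0.09 (Cdh5 0.19, Pecam1 -0.12) and stellate cell markers 0.0032 (Pdgfrb -0.31, Vim -0.23), where the mean was -0.014 and camera's direction down. Cholangiocyte markers had -0.19, led by Spp1 at -1.19 ± 0.46 and Cftr at -0.46. Exocrine pancreas markers had a median of -0.18 (Prss2 0.32, Cela2a -0.43, the last above background on 1 of 3 isoflurane arrays). Only 3 adipocyte and mesothelium markers were measured and are given as values, with Fabp4 at 0.86 and Cidec at -0.12.

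Genes of rapid stress and hormone responses gave no list past the threshold with either correlation. Immediate early genes, switched on within minutes of a stimulus, had a median of 0.12 (14 of 19 higher; camera adjusted p = 0.185). Myc was the member past the threshold over the list alone, at -1.0 ± 0.19, while Ier3 had 0.62 ± 0.15 and Egr1 1.74 ± 0.78. Glucocorticoid-induced genes had a median of -0.18 (11 of 17 lower), with Zbtb16 past the threshold over the list alone and Lcn2 at -0.74 ± 0.33. cAMP-responsive genes had -0.08 (Sik1 0.75 ± 0.48, Pde4d -0.32 ± 0.20). Hypoxia-induced genes had 0.01 (Car9 0.27 ± 0.086, Ankrd37 0.74 ± 0.27; adjusted p = 0.694). Carbonic anhydrase and acid-base genes, which handle CO2 and bicarbonate, had 0.02 (8 higher and 8 lower, with Slc4a4 -0.52 ± 0.15, Car3 0.98 ± 0.33, Car8 0.47 ± 0.17). The values of both groups did not overlap for 8 of these 16 genes, against 14.2% of all genes. In limma 4 of the 16 had an unadjusted p under 0.05, against 7.5% of all genes, and 0 passed over the list alone. Fry's test for change in either direction gave this list adjusted p = 0.125. Heat shock genes had 0.03 (Hspb1 1.03 ± 0.65, Cryab -0.28 ± 0.15). Unfolded protein and integrated stress response genes had 0.14 (Dnajb9 0.28 ± 0.11, Sesn2 -0.39 ± 0.21). Genes of p53 and growth arrest had 0.07, with Gadd45a past the threshold over the list alone at -0.44 ± 0.096 and Mdm2 at 0.35 ± 0.11. Acute phase and inflammatory genes had -0.05 (Cebpd -0.52 ± 0.18), and cell cycle genes 0.17 (12 of 16 higher, adjusted p = 0.149; Birc5 0.56 ± 0.27, Aurka 0.22 ± 0.16). The mean of the cell cycle list was 0.55 on isoflurane replicate 2, against -0.27 and -0.01 on the other isoflurane arrays. Its median was -0.06 without that array (adjusted p = 0.712), 0.36 without isoflurane replicate 1 (adjusted p = 0.000538) and 0.24 without CO2/O2 replicate 1 (adjusted p = 0.0163).

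Of 14 circadian clock genes, 8 had positive and 6 negative differences, and 0 passed over the list alone. In limma, 7 of the 14 had an unadjusted p under 0.05, against 7.5% of all genes tested. The values of both groups did not overlap for 7 of the 14, against 14.2% of all genes. Bmal1 and Npas2, of the activating limb, had log2 differences of -1.22 ± 0.49 and -0.60 ± 0.32. Both leaned on isoflurane replicate 3. On isoflurane replicates 1 to 3 the signals were 0.01, 0.56 and -1.48 for Bmal1 and -0.38, -0.58 and -1.61 for Npas2. Dbp (0.87 ± 0.28), Per2 (0.69 ± 0.20), Nr1d1 (0.62 ± 0.23), Per3 (0.43 ± 0.16), Tef (0.37 ± 0.12) and Nr1d2 (0.37 ± 0.10), of the output and repressing limbs, had positive differences. Other repressors had -0.34 ± 0.42 (Per1), -0.15 ± 0.27 (Nfil3), -0.07 ± 0.14 (Cry1) and 0.06 ± 0.21 (Cry2). The list median was 0.14, and 0.03 to 0.26 with an array left out. Camera, which looks for a shift of the list in 1 direction, gave adjusted p = 0.185. Fry's test for change in either direction gave adjusted p = 0.144. Apart from Per2 and Nr1d2, these clock genes were named after their values were seen.

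The lists of xenobiotic and metabolic genes had medians within 0.2 of 0, and none of those tested passed. CAR and PXR targets, which encode drug-metabolising enzymes, had a median of 0.02 (10 of 18 higher; Cyp2b2 0.50 ± 0.17, Cyp3a18 0.77 ± 0.28), in families of similar sequence. AhR targets were measured for 4 genes, given as values only, where Nqo1, an NAD(P)H quinone oxidoreductase, had -0.91 ± 0.23 and passed over the list alone, and Aldh3a1 had -0.10 ± 0.089. Nrf2 targets, a list that also holds Nqo1, had -0.04 (Srxn1 -0.39 ± 0.16, with 0.07 at its other probe). Glucose metabolism genes had a median of -0.0018 and a mean of 0.019, with camera's direction up (Pfkl 0.19 ± 0.099, Irs2 0.21 ± 0.12). Cholesterol synthesis genes had 0.01 and a mean of -0.07, with camera's direction down; Insig1 was the 1 member past the threshold over the list alone and Fdft1 had 0.15 ± 0.084. Fatty acid synthesis genes had -0.02 (Gpam -0.44 ± 0.20, Acaca 0.23 ± 0.14), and PPAR alpha targets 0.04 (Cyp4a2 0.65 ± 0.33). Bile acid genes had -0.14 (8 of 12 lower), with Slc27a5 past the threshold over the list alone and Nr1h4, the bile acid receptor, at -0.36 ± 0.16. Growth hormone and male-pattern genes had a median of 0.06 and a mean of -0.32, with camera's direction up. The mean was pulled by Akr1b7 at -5.62 ± 1.65, above background on 1 of 3 isoflurane arrays, and Socs2 had -1.07 ± 0.36.

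Hepatocyte markers had a median of 0.03 (Hnf4a 0.38 ± 0.18, Cyp2e1 -0.28 ± 0.16), and reference genes -0.01, with Gusb at -0.15 ± 0.089. Periportal markers had -0.08 (Hal -0.25 ± 0.15, Cps1 -0.27 ± 0.21), pericentral markers -0.22 (7 of 9 lower; Oat -0.54 ± 0.25, Slc1a2 -0.30 ± 0.16) and urea cycle genes -0.06 (Slc25a15 -0.15 ± 0.088, with 0.05 at its other probe). Over all 34 lists, 32 were tested, 2 passed with the preset correlation, 0 with an estimated correlation and 0 with limma's fry for change in 1 direction. At an unadjusted p under 0.05 there were 6, 0 and 1. Fry's test for change in either direction passed for 3 lists, the hypoxia-induced, bile acid and p53 genes. How well that test holds with 3 rats per group was not checked. Of 368 list genes, 0 passed over all probes, and 27 of the 34 lists had no member past the threshold over the list alone.

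**Figure D3:**
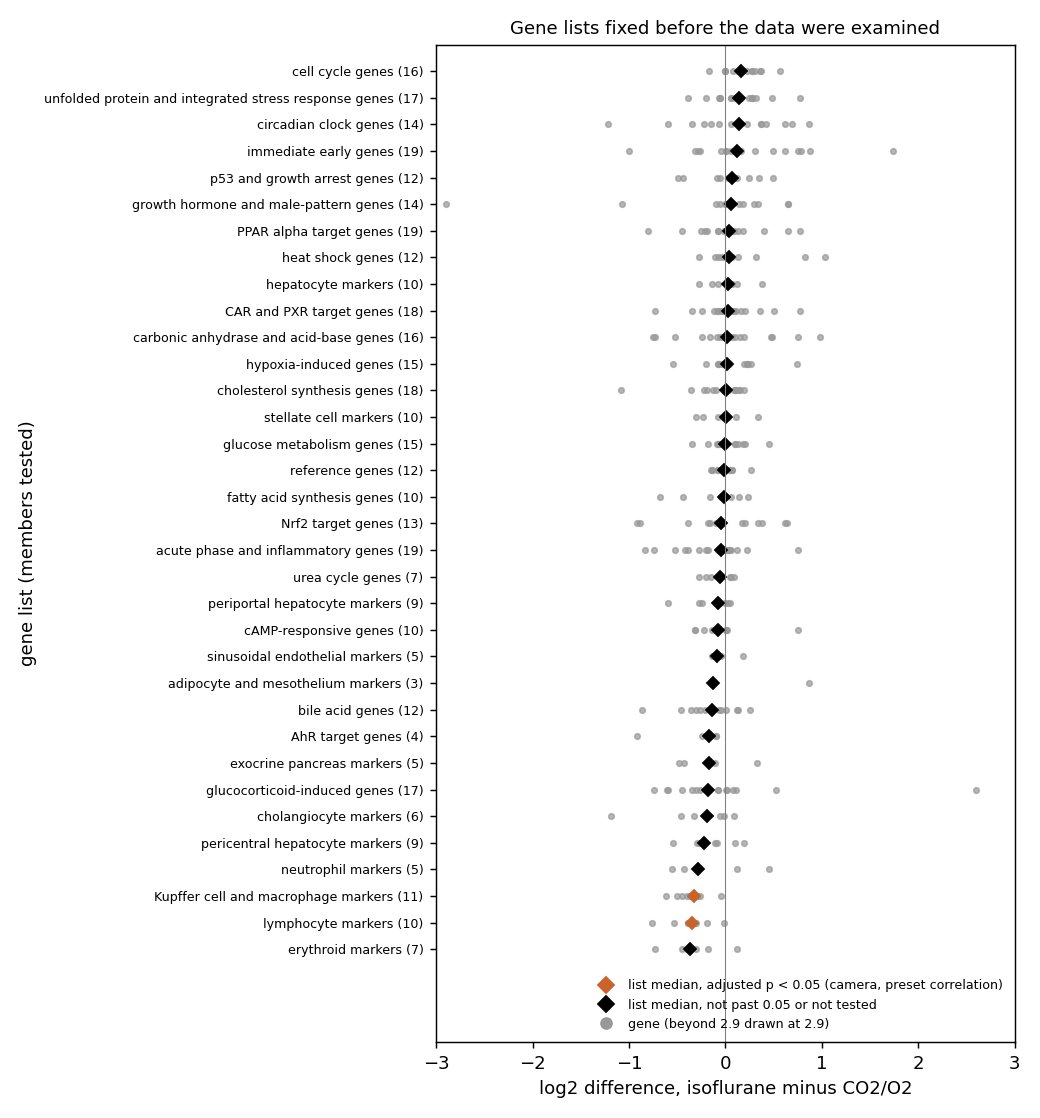
Log2 differences, isoflurane minus CO2/O2, of the measured members of 34 gene lists (grey points are genes, diamonds are list medians; number of members in brackets; Akr1b7, at -5.62, is drawn at the axis limit). The medians of 27 tested lists lie within 0.2 of 0. Kupffer cell and lymphocyte lists, in orange, passed camera with the preset correlation. With an estimated one they had adjusted p = 0.921, as had all tested lists.

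Whole expression profiles were highly correlated between rats. Pearson correlations over probes, which are not independent replicates, were 0.991 to 0.994 among CO2/O2 rats, 0.984 to 0.989 among isoflurane rats and 0.982 to 0.993 between groups. The mean distance between arrays was 0.467 between groups, 0.369 within CO2/O2 and 0.496 within isoflurane. The mean distance between groups less that within groups was 0.0342, with a 1-sided exact permutation p = 0.1 for separation. That is the smallest p that 10 splits of the 6 arrays allow. The first 3 principal components carried 34.7%, 26.1% and 16.4% of the variance. On the first, CO2/O2 arrays had scores of -39.3, -23.5 and -7.44 and isoflurane arrays -4.28, 11.4 and 63.1, an order that is also that of the arrays' places on the slide. Without CO2/O2 replicate 1 the difference in distance was -0.0130, and without CO2/O2 replicate 2 it was -0.00497.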

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

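The fry test for change in either direction was looked at after the data were seen. The count of probes past the threshold, 3, was 5 with normexp and with eBayes trend and robust, 1 with no filter on dim probes, 0 with the replicate block, 2637 at an unadjusted p, and 1 to 20 when each array was left out (20 without CO2/O2 replicate 3, 17 without isoflurane replicate 1, 5 without isoflurane replicate 2, 1 without CO2/O2 replicate 1 or isoflurane replicate 3). The count of genes, 0, was 1 with the slide row as a block, 799 at an unadjusted p, and 0 to 8 with an array left out (8 without isoflurane replicate 1, 4 without CO2/O2 replicate 3). The count of lists, 2, was 5 with median centring, 1 with the slide row as a block, 0 with an estimated correlation, 0 with fry, and 1 to 4 with an array left out (4 without CO2/O2 replicate 1 or isoflurane replicate 1, 1 without isoflurane replicate 3). The Kupffer cell call ended with an estimated correlation (adjusted p = 0.921) and with fry (0.544). In the other alternatives adjusted p lay between 3.49e-09 and 0.000536, leaving aside the slide row block (0.00343), whose isoflurane arm is 1 rat assumed to vary like the rest. With median centring the immediate early, clock and cell cycle lists also passed, as did the immediate early list without isoflurane replicate 1 (median 0.29, adjusted p = 0.00707) and the clock list without CO2/O2 replicate 1 (median 0.21, adjusted p = 0.0283). With an array left out, the medians of 18 of the 32 tested lists took both signs, among them glucocorticoid (-0.38 to 0.07), bile acid (-0.24 to 0.04) and cholesterol synthesis genes (-0.16 to 0.22). Neutrophil markers ran from -0.66 to -0.09, exocrine pancreas from -0.45 to -0.06, cholangiocyte from -0.29 to -0.07 and pericentral from -0.26 to -0.12. The cAMP-responsive list ran from -0.24 to -0.03 and the unfolded protein list from 0.06 to 0.25. The difference in distance ran from -0.0130 to 0.0903 with an array left out. It turned negative without CO2/O2 replicate 1 or 2 (-0.00497 for the latter). With the slide row as a block, where isoflurane replicate 1 alone is set against the CO2/O2 rats, 7 named genes changed sign: Hspb1 -0.0075, Cps1 0.104, Hal 0.036, Pecam1 0.065, S100a9 0.178, S100a8 0.340 and Cela2a 0.166. The cause was not tested. Fry's test for change in either direction passed for 3 lists, hypoxia-induced (adjusted p = 5.46e-05), bile acid (0.000687) and p53 genes (0.00562). No member of these lists passed over all probes, and how well that test holds at 3 against 3 was not checked. Replicate numbers gave no clear pairing of the samples. Deviations correlated at 0.11, 0.02 and 0.06 between same-numbered arrays and at -0.09 to 0.04 between the others. CO2/O2 replicate 2 correlated best with isoflurane replicate 3 (0.037). With 3 rats per group these values cannot exclude a weak pairing. The replicate block gave 0 probes, 0 genes and 3 lists. Signal over background and 3 rats per group limit all of these, and blocks for slide and scan date were not run, since there was 1 slide and 1 scan time.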

Other observations

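The tests of cell composition and array place below, and the genes of the first paragraph, were chosen after the results were seen. The rule deciding how the place test is read was also revised after its value was seen, since it at first allowed no reading in favour of the explanation. That of the clock test was changed more than once after its value was seen, and the final reading asks that the sign hold without each array.

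Single rats differed widely in hepatic genes under either anaesthesia. Ugt2b, a glucuronosyltransferase of a family of close paralogs, had log2 signals of 2.62, 8.14 and 7.32 on the CO2/O2 arrays and 2.74, 7.98 and 2.47 on the isoflurane arrays, a range of 50.7-fold with low and high rats in both groups. Ubd, a ubiquitin-like protein, was low on CO2/O2 replicate 3 alone (-3.43, against 2.45 to 4.0 elsewhere), a range of 173-fold. Igfbp1, a fasting- and insulin-responsive binding protein, ranged 14.3-fold (1.54, 4.09 and 4.38 on CO2/O2 arrays; 2.84, 1.40 and 5.24 on isoflurane arrays). Fgf21, a hepatic fasting hormone, ranged 16.0-fold, from 0.76 on CO2/O2 replicate 1 to 4.76 on isoflurane replicate 3. Bcl6, a transcriptional repressor, ranged 15.5-fold and Acot1 16.2-fold. Noct, a rhythmic gene, ranged 23.6-fold, with an SD of 0.334 log2 units in CO2/O2 rats and 2.34 in isoflurane rats. The median SD per gene was 0.113 log2 units in CO2/O2 rats and 0.14 in isoflurane rats.

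For the lower macrophage markers after isoflurane, a smaller share of all non-parenchymal cells was examined by the macrophage mean less the endothelial and stellate mean. It was -0.3276 (SE 0.095, exact permutation p = 0.1, the smallest possible), so endothelial and stellate markers were not lower to the same degree. The lymphocyte list had a mean difference of -0.36, near the -0.35 of the macrophage list. The cholangiocyte list had -0.33, a mean pulled by Spp1 at -1.19, with a median of -0.19. The test left lymphocytes and cholangiocytes out, so it does not decide on all non-parenchymal cells. Blood cells left in the liver as the sole source would leave markers of resident Kupffer cells unchanged. The mean of 5 such markers was -0.3843 (SE 0.144, exact permutation p = 0.1). These are members of the list that prompted the test and were already seen to be lower, so the test does not decide on that source. The difference was also within 2 standard errors of 0 without CO2/O2 replicate 1 (-0.27, SE 0.143) or 2 (-0.37, SE 0.244). The 22 blood cell markers had a mean difference of -0.3009 (SE 0.219). Place, counted along slide row 1 and then on along row 2, may account for the pattern. Marker means had negative slopes over places within both groups (-0.196 and -0.0684 per place). After a shared slope the group difference was 0.04645 (SE 0.141). This count is an order of arrays and not a distance, since row 2 starts again at the first position. Place is nearly confounded with group, so a biological difference, such as fewer or less active Kupffer cells after isoflurane than after CO2/O2, stays open and untested. Without a group free of anaesthesia, it could not be assigned to either kind.

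Opposite values of Bmal1 and Dbp could reflect a different clock phase, such as rats killed at different hours. Usp2, Wee1 and Nampt, outside the list and expected to follow Dbp, had a mean difference of -0.1126 (SE 0.186, exact permutation p = 0.7). This lies on the side set beforehand as against a shift of phase, which was a lower value or a rise smaller than the standard error. Without isoflurane replicate 2 the difference is 0.067 (SE 0.082), still on that side but with the other sign. Both standard errors are larger than their differences, so the test does not decide and the explanation stays open. Times of killing are not given in the sources used here.

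Probes with at least 2 log2 units between the nearest values of the 2 groups numbered 2 for the real groups and up to 6 in the other splits of the arrays. This is consistent with differences between single outbred animals, and no other explanation was tested for these probes. The 10 splits of 6 arrays are too few for a share under 0.05. Counting the real split, 3 splits gave as many probes past the threshold (real 3, highest other 8) and 9 as many lists (real 2, highest other 9). For genes the real count of 0 makes all 10 splits reach it, so that tally carries no information (highest other 1). Probes at an unadjusted p under 0.05 numbered 2637 in the real split, the most of the 10, against at most 2281 elsewhere. The macrophage list was called in 3 of the 9 other splits. With an estimated correlation, 0 lists were called in each of the 10 splits.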
